A study of Mus musculus with 13 samples.

How the data were processed

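Whole bone marrow of transplanted mice was measured on 13 Affymetrix expression arrays in 3 groups, taken from the sample labels: BRSST+sgEzh2 (4 arrays), BRSST+sgLuc (5 arrays) and sgLuc (4 arrays). Per the labels' protocols, RNA was isolated with a Zymo kit, and 2 ng was amplified with a Pico kit using 10 PCR cycles before in vitro transcription, a step that can compress or distort large differences. Nothing in the labels says that each array came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

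The deposited values are log2 signals, 1 per row and array, which the authors made with R 3.5.01 and oligo, per the submitters' processing notes. The background correction, the normalization and the oligo version are not given in the sources used here. That the scale is log2 was read from the values, which lie between 3.23 and 13.75 with array medians from 7.19 to 7.32. Signals near the top of such a range can be compressed. Arrays have no read depth, and their number limits the precision.

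Of 22203 rows, 19572 had 1 gene symbol, 0 had several and 2631 had none. The symbols were checked by Entrez number against a RefSeq gene table of the assembly GRCm38.p6, used only for names and for which genes neighbour each other, and 0 symbols changed. For the 55 of 19505 symbols with more than 1 row, the row with the highest mean was used. A gene was tested if it lay above its array's median in at least 4 arrays, which left 10601 genes.

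Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 13 arrays with no covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a gene is from limma. Ezh2 was also given an exact two-sided permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

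Of 28 gene lists written from textbook knowledge, 27 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with the correlation estimated per list and fry, also from limma, were run beside it. No list passed with an estimated correlation in any comparison (smallest adjusted p 0.387, 0.0666 and 0.0898). The list of X-inactivation and Y-linked genes had 2 measured members, Uty and Kdm5d, and was not tested. Their mean signal split the arrays at log2 6.09 into a high and a low class.

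Named genes followed a rule. It took the 10 largest rises and 10 largest falls of each comparison among genes past the threshold whose groups did not overlap, or all where fewer passed, leaving out symbols made of Gm and digits, ending in Rik or starting with Mir, Snor, LOC, AU, AI, BC, AK or n-R, and single V, D or J segments. It added Ezh2, every changed PRC2 subunit, Hox gene and myeloid tumour suppressor, and per list up to 4 changed members with the largest change, or the 2 with the smallest p where none changed. Not every list member so taken is described, and 1 of the largest rises is not reported here. Clock, Arntl, Chchd7, Penk, Fkbp5, Klf9 and Mt1 were chosen after their values were seen, as were Per1 and Tsc22d3 from a list of glucocorticoid-induced genes written before its values were.

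The procedure was tested on simulated data of 10601 genes. Of genes changed by log2 1, 86%, 85% and 77% were recovered for BRSST+sgEzh2 against BRSST+sgLuc, BRSST+sgLuc against sgLuc and BRSST+sgEzh2 against sgLuc, and 99% of those changed by log2 2 in each. False calls made up 5.61%, 3.66% and 3.3% of calls. Each simulated gene had the same spread in all 3 groups. The real median SD was 0.188 in BRSST+sgEzh2, 0.248 in BRSST+sgLuc and 0.154 in sgLuc, so rates in the real data can differ. A shifted list was called in 20 of 20 simulations, and 1 of 520 unchanged lists was called, in each comparison. The simulated genes varied independently, while the real lists had a median estimated correlation of 0.221. The simulation therefore cannot show how often camera calls an unchanged list of correlated genes.

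Alternatives were no filter and a stricter one (the 75th percentile), quantile normalization, equal medians, the mean of a gene's rows, trended and robust variance, array quality weights, the replicate number as a block, only the 2 groups compared, stricter thresholds, and each array left out in turn. Chosen after seeing the data were the Y-linked class as a block, each class alone, list scores as covariates, and a fit without BRSST+sgLuc replicates 2 and 5, the arrays farthest apart on the second principal component. Rows without a symbol were left out of the comparisons.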

Results

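Whole bone marrow RNA was profiled on 13 Affymetrix expression arrays. The marrow came from C57Bl/6J mice irradiated with 7 Gy and transplanted 24 h after guide transduction with LSK cells of Cas9 knock-in mice, a marrow fraction enriched in haematopoietic stem and progenitor cells. Harvest followed signs of leukemia or came after 6 months, and which sample belongs to which case is not given in the sources used here. There were 4 arrays of BRSST+sgEzh2, 5 arrays of BRSST+sgLuc and 4 arrays of the control guide sgLuc alone. BRSST is the submitters' name for a guide combination and is not spelled out in the labels. Median log2 signal ran from 7.19 to 7.32 across arrays, and mean correlation between arrays of a group was 0.963 for BRSST+sgEzh2, 0.939 for BRSST+sgLuc and 0.978 for sgLuc. The first principal component held 39.5% of the variance and put the sgLuc arrays at 27.5 to 34.3, with every array of both BRSST groups below 0. Uty and Kdm5d, which lie on the Y chromosome, were high on 2 of 4 BRSST+sgEzh2 arrays, 2 of 5 BRSST+sgLuc arrays and 4 of 4 sgLuc arrays. Between BRSST+sgLuc and sgLuc, Kdm5d differed by log2 -2.07 ± 0.73 (limma adjusted p = 0.0559, and 0.0424 or 0.0422 without BRSST+sgLuc replicate 1 or 4) and Uty by -1.92 ± 0.81 (0.104). Label numbers ran on through both BRSST groups and restarted later for sgLuc, so an array batch and the sgLuc group cannot be told apart.

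Ezh2, the histone H3 lysine methyltransferase of Polycomb repressive complex 2 (PRC2) and the target of the added guide, had the lowest transcript signal in BRSST+sgEzh2 marrow. Its mean log2 signal was 8.78 ± 0.50 (SD, n = 4) with BRSST+sgEzh2, 9.82 ± 0.50 (SD, n = 5) with BRSST+sgLuc and 10.35 ± 0.28 (SD, n = 4) with sgLuc. BRSST+sgEzh2 arrays ranged from 8.08 to 9.22 and BRSST+sgLuc arrays from 9.15 to 10.46, so the groups overlapped. The difference was -1.05 ± 0.26 (log2, SE), or 48.4% of the BRSST+sgLuc level, with limma adjusted p = 0.0808 and a two-sided exact permutation p = 0.0238 over 126 splits. Leaving out BRSST+sgLuc replicate 5 moved the limma adjusted p to 0.0414, with a difference of -1.21. Against sgLuc, Ezh2 fell by 1.57 ± 0.28 in BRSST+sgEzh2 marrow, to 33.6% of the control level (limma adjusted p = 0.00306, exact permutation p = 0.0286 over 70 splits). BRSST+sgLuc against sgLuc gave -0.53 ± 0.26, which did not pass (limma adjusted p = 0.172, exact permutation p = 0.111). A guide edit need not lower transcript abundance, and the probes need not lie at the edited site, so this signal checks the labels only in part.

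**Figure D1:**
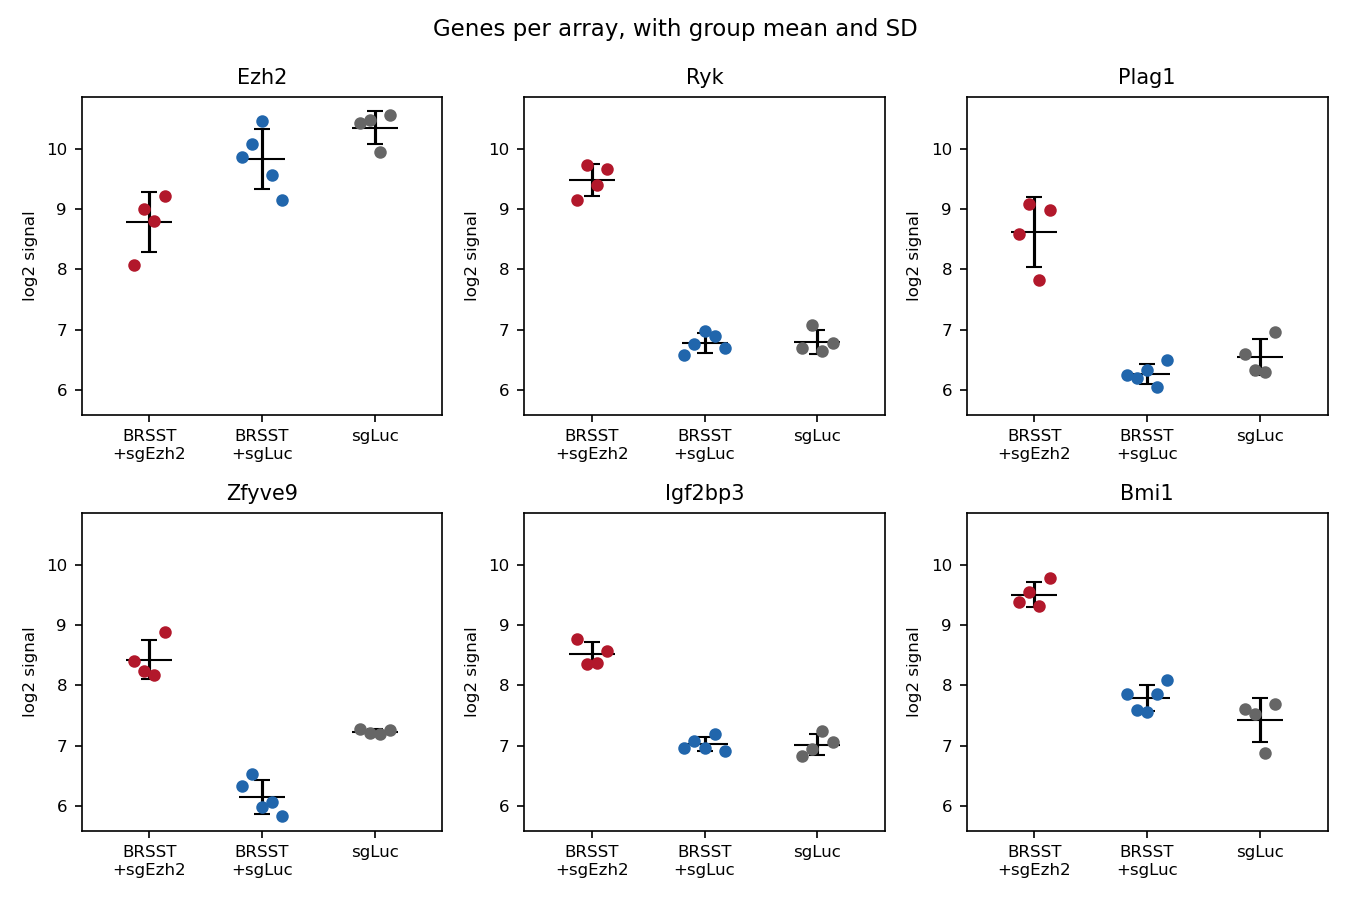
Log2 signal of 6 genes on each array (points) by group, with the group mean and SD (black). Ezh2 averaged 8.78, 9.82 and 10.35 in BRSST+sgEzh2, BRSST+sgLuc and sgLuc, and Ryk averaged 9.48, 6.78 and 6.80, with no overlap between BRSST+sgEzh2 and the other groups for Ryk, Plag1, Zfyve9, Igf2bp3 or Bmi1.

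Most genes that passed between BRSST+sgEzh2 and BRSST+sgLuc, the comparison that asks what the Ezh2 guide changes on the BRSST background, were higher in BRSST+sgEzh2. Ryk, a Wnt-binding receptor of the receptor tyrosine kinase family, rose most, by log2 2.70 ± 0.14 (SE, n = 4 and 5), or 6.5-fold. Plag1, a zinc finger transcription factor and known oncogene, rose 5.11-fold (log2 2.35 ± 0.22), and Zfyve9, an endosomal adaptor of TGF-beta receptor signalling, rose 4.86-fold (log2 2.28 ± 0.16). Bmi1, a subunit of Polycomb repressive complex 1, rose 3.28-fold (log2 1.71 ± 0.17). Igf2bp3, an RNA-binding protein of fetal tissues, rose 2.8-fold (log2 1.49 ± 0.12). Limma adjusted p was 2.11e-07 for Ryk, 0.000136 for Plag1, 5.7e-06 for Zfyve9, 0.000192 for Bmi1 and 2.16e-05 for Igf2bp3. Dip2c (log2 2.54), Krt80, a keratin (2.13), Gpr35, a G protein-coupled receptor (1.86), Mybl1, a MYB family transcription factor (1.68), and Apoc1, an apolipoprotein (1.57), were among the other large rises. Ube2l6, the conjugating enzyme for ISG15, fell by 1.57 ± 0.24 (adjusted p = 0.00692), Il1r2, the decoy receptor of interleukin 1, fell by 1.36 ± 0.24 (0.0202) and Syngr1, a vesicle membrane protein, fell by 1.08 ± 0.16 (0.00692). Smaller falls were those of Wdr73 (-0.74), Osgepl1, a tRNA-modifying enzyme (-0.71), Hoxa5 (-0.60), Ginm1 (-0.58), Ctdspl (-0.55) and Msantd3 (-0.52). In all, 83 of 10601 genes passed limma's test at an adjusted p of 0.05, 71 higher and 12 lower, and 32 rose and 5 fell by at least 2-fold. With the medians of the arrays set equal, 75.4% of the calls were rises in place of 85.5%. Groups did not overlap for 3.53% of genes, against 1.59% by chance. The count rested on single arrays: it was 22, 36 or 47 without BRSST+sgEzh2 replicate 4, 1 or 3, 29 or 34 without BRSST+sgLuc replicate 1 or 4, and 257 or 377 without BRSST+sgLuc replicate 2 or 3. With B lineage, monocyte and erythroid scores as covariates it was 2. With only the 2 groups compared limma called 17 genes, all higher, while 790 were higher and 316 lower at an unadjusted p under 0.05. With array quality weights 694 rose and 345 fell, 66.8% rises. Of the 71 higher genes, 30 also rose and 3 fell against sgLuc, and 35 fell in BRSST+sgLuc against sgLuc. These counts reuse arrays on which the 71 were chosen, so part of each can follow from that choice. Signals of BRSST+sgEzh2 overlapped those of sgLuc for Krt80, Gpr35 and Mybl1, and lay above them for the other rises named here. Among the named falls they lay below sgLuc only for Ube2l6 and Ctdspl, and overlapped it for the rest.

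Among these genes the calls of Ryk, Dip2c, Plag1, Zfyve9, Gpr35, Bmi1, Igf2bp3, Ube2l6 and Syngr1 held in each of the 9 fits that left out 1 array. With only the 2 groups compared, Ryk, Dip2c, Plag1, Zfyve9, Gpr35, Bmi1, Igf2bp3 and Mybl1 kept their calls (limma adjusted p of up to 0.045), while Ube2l6 and Syngr1 (0.0557 each), Apoc1, Krt80 and the other 7 named falls lost theirs (up to 0.159). That of Mybl1 ended without BRSST+sgEzh2 replicate 4 (limma adjusted p = 0.067). Apoc1 lost its call without BRSST+sgEzh2 replicate 1 or 4 or BRSST+sgLuc replicate 1 (up to 0.088), and Il1r2 without BRSST+sgEzh2 replicate 1 or 3 or BRSST+sgLuc replicate 1 or 4 (up to 0.0684). Krt80, Hoxa5, Wdr73, Osgepl1, Ginm1, Ctdspl and Msantd3 each lost theirs without any of 4 to 7 arrays, BRSST+sgEzh2 replicate 4 and BRSST+sgLuc replicates 1 and 4 always among them, with adjusted p of up to 0.13.

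The erythroid list was lower and the monocyte and macrophage list higher in BRSST+sgEzh2 by camera, neither with an estimated correlation. Of 17 measured erythroid genes, 16 were lower, none passed the test over all genes and 8 fell when adjusted over the list alone. Ank1, a red cell membrane anchor, differed by -1.001 ± 0.27 (limma adjusted p = 0.103, and 0.0419 without BRSST+sgLuc replicate 5) and Car2, a carbonic anhydrase, by -1.10 ± 0.33 (0.145). The erythroid score, the mean log2 signal of the list, was 7.93 ± 0.20 (SD, n = 4) with BRSST+sgEzh2, 8.47 ± 0.27 (SD, n = 5) with BRSST+sgLuc and 7.80 ± 0.14 (SD, n = 4) with sgLuc. The list passed limma's camera test (adjusted p = 2.13e-07 over 27 lists), but not with an estimated correlation between genes (adjusted p = 0.387). Of 21 monocyte and macrophage genes 1 rose over all genes, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 9.91e-05, and 0.626 with an estimated correlation). Mpeg1, a pore-forming protein of macrophages, rose by log2 1.38 ± 0.28 (adjusted p = 0.0371). In the mast cell, basophil and eosinophil list, Siglecf, a lectin of eosinophils, rose by 0.97 ± 0.21 (0.0472), while the list itself did not pass (camera adjusted p = 0.924). The calls of Mpeg1 and Siglecf each ended without any of 6 arrays, BRSST+sgEzh2 replicate 4 and BRSST+sgLuc replicates 1 and 4 among them (adjusted p of up to 0.137), and also with only the 2 groups compared (0.146 and 0.164).

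Known PRC2-silenced genes had 2 rises among 11 measured, Plag1 and Igf2bp3, and the same 2 adjusted over the list alone. The list was up by camera (adjusted p = 0.0452, and 0.603 with an estimated correlation), with a median of log2 0.03 beside a mean of 0.40, and the median turned to -0.032 with quantile normalization, where the call ended (0.0623), and to -0.037 with equal medians. It lost its call without BRSST+sgEzh2 replicate 1 or 3 or BRSST+sgLuc replicate 2, 3 or 5 (adjusted p from 0.0529 to 0.234). Of 12 Hox genes and cofactors, 1 fell, Hoxa5, and 3 fell when adjusted over the list alone (camera adjusted p = 0.0128, 0.603 with an estimated correlation, 0.0532 without BRSST+sgEzh2 replicate 4). No member of the T and NK cell or B lineage lists passed, over all genes or adjusted over the list alone, though 16 of 17 and 17 of 20 were higher. Il2rb, an interleukin receptor chain, differed by log2 1.74 ± 0.64 (limma adjusted p = 0.235, and 0.0154 without BRSST+sgEzh2 replicate 1) and Zap70, a T cell receptor kinase, by 0.63 ± 0.24 (0.249). Camera adjusted p was 0.00809 for the T and NK list (0.849 with an estimated correlation, 0.652 without BRSST+sgEzh2 replicate 3 and 0.0601 without BRSST+sgLuc replicate 3) and 0.0484 for the B lineage list (0.972 with an estimated correlation, and up to 0.652 without 1 of 6 arrays, BRSST+sgEzh2 replicates 2 and 3 and BRSST+sgLuc replicates 1, 3, 4 and 5).

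Of 25 glycolysis and hypoxia genes 21 were higher, none passed over all genes and 3 rose when adjusted over the list alone (camera adjusted p = 0.016, and 0.603 with an estimated correlation). Pfkl, a phosphofructokinase, differed by log2 0.62 ± 0.15 (limma adjusted p = 0.0641) and Hk2, a hexokinase, by 0.81 ± 0.22 (0.105), and both passed without BRSST+sgLuc replicate 3 (0.00613 and 0.0148). Of 17 cholesterol synthesis genes 15 were higher and 0 passed, also adjusted over the list alone (camera adjusted p = 0.0116, 0.603 with an estimated correlation, 0.194 without BRSST+sgLuc replicate 5). Stard4, a sterol carrier, was at 0.99 ± 0.42 and Dhcr7, the last enzyme of the pathway, at 0.32 ± 0.14, with adjusted p of 0.312 and 0.313. The Stard4 difference leaned on BRSST+sgEzh2 replicate 3, with a log2 signal of 9.734 where the next of its group was 7.774. Of 26 oxidative phosphorylation genes 17 were lower and 0 passed, also adjusted over the list alone, with Sdhd at -0.31 ± 0.10 (0.165) and Sdha at 0.62 ± 0.23 (0.242). That list had a camera adjusted p of 0.021 (0.849 with an estimated correlation), lost without BRSST+sgEzh2 replicate 3 or BRSST+sgLuc replicate 1, 2 or 3 (up to 0.112), and the glycolysis list was lost without BRSST+sgEzh2 replicate 3 or BRSST+sgLuc replicate 2 (up to 0.096). The remaining 18 of the 27 lists had camera adjusted p from 0.149 to 0.938, among them the PRC2 subunits (0.924), where 0 of 11 members passed and Ezh2 alone fell when adjusted over the list alone. Fry called 1 list, the known PRC2-silenced genes (adjusted p = 0.0416), and gave 0.054 for the erythroid list. Signs of the median, the mean and the test did not all match for the primary granule, mature neutrophil, megakaryocyte, dendritic cell and immediate early lists.

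BRSST+sgLuc marrow, set against sgLuc marrow to ask what the BRSST guides change, had its largest falls in Prss34, Vpreb3 and Vpreb1. Leukemia and time of harvest are not given per sample, and an array batch would coincide with sgLuc. Differences from sgLuc can therefore not be assigned to the guides alone. Prss34, a protease of mast cells and basophils, fell by 4.76 ± 0.22 on the log2 scale (SE, n = 5 and 4), and was 27.04-fold lower. Vpreb3 (-4.24 ± 0.63), a gene of B cell precursors, and Vpreb1 (-3.96 ± 0.74), part of the pre-B cell receptor, fell 18.9-fold and 15.6-fold. Il7r, the receptor of a lymphoid growth factor, fell 10.6-fold (-3.41 ± 0.54). On BRSST+sgLuc replicates 1, 3, 4 and 5 the Il7r signal (4.497 to 5.345) lay below the lower quartiles of those arrays (5.673 to 5.804). The size of its fold is therefore uncertain. Jchain, the joining chain of polymeric antibodies (-3.75), Siglech, a lectin of plasmacytoid dendritic cells (-3.57), Slamf7 (-3.68), Il1rn, the interleukin 1 receptor antagonist (-3.69), Atp1b1, a sodium pump subunit (-3.70), and Tlr5, the flagellin receptor (-3.31), also fell. Limma adjusted p for these genes lay between 3.54e-08 for Prss34 and 0.00234 for Vpreb1. Among stefins, inhibitors of cysteine proteases, Cstdc5 rose by 2.89 ± 0.21, Stfa1 by 2.80 ± 0.19, Stfa2 by 2.77 ± 0.20, Csta2 by 2.47 ± 0.21 and Cstdc6 by 2.46 ± 0.24. These paralogs have near-identical sequences and their probes can share signal, so the split among them is uncertain. Ces2g, a carboxylesterase, rose most among genes whose groups did not overlap, by 3.35 ± 0.32 or 10.2-fold. Saa3, an acute phase protein, rose by 2.88 ± 0.65, Cd14, a co-receptor for lipopolysaccharide, by 2.54 ± 0.25, and the erythroid genes Car1 and Rhag by 2.58 ± 0.53 and 2.55 ± 0.38. In all, 2389 of 10601 genes passed limma's test, 1149 higher and 1240 lower, and 117 rose and 360 fell by at least 2-fold. Groups did not overlap for 18.9% of genes, against 1.59% by chance. The count was 1481 without sgLuc replicate 1, and 7 with B lineage, monocyte and erythroid scores as covariates, which separate these groups.

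**Figure D2:**
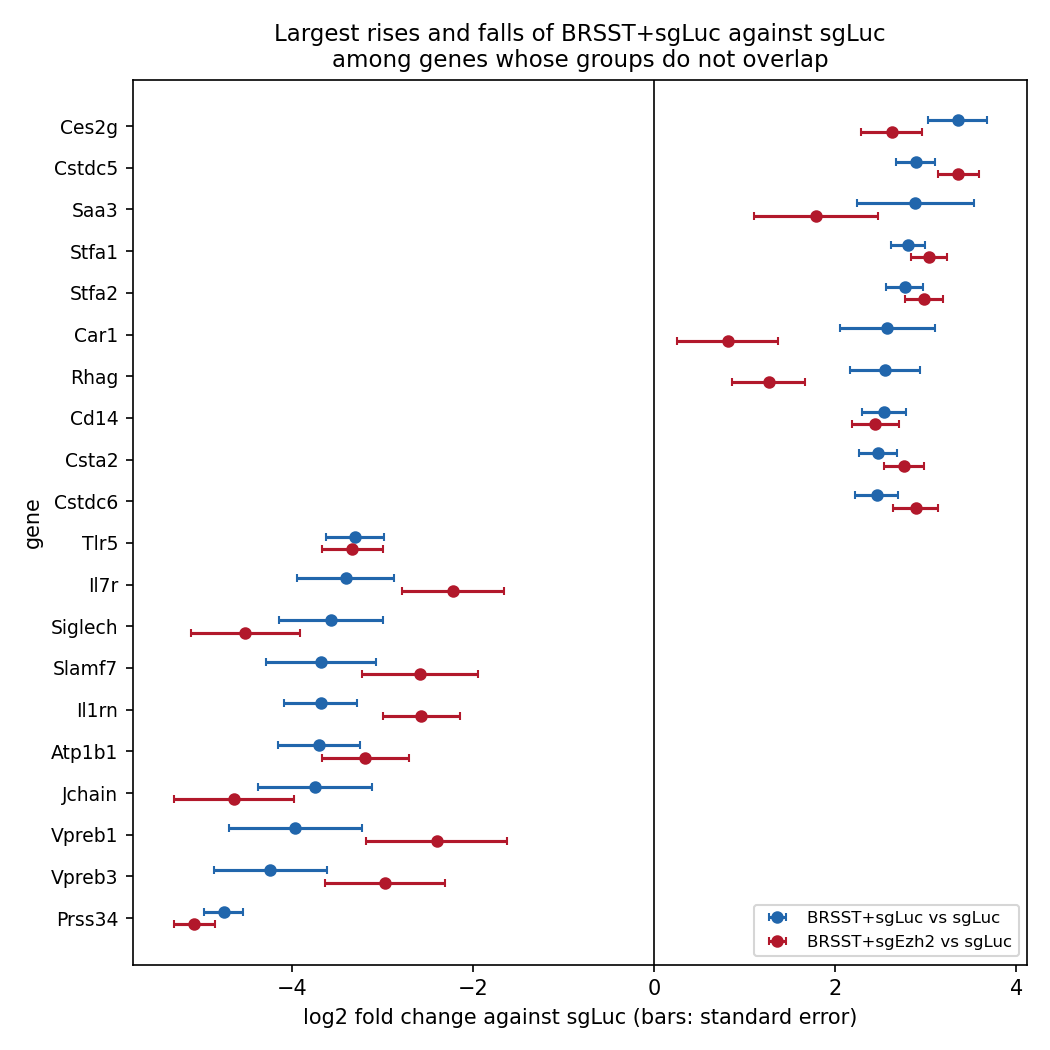
Log2 fold change against sgLuc, with standard error, of the 10 largest rises and 10 largest falls of BRSST+sgLuc among the named genes whose groups did not overlap, shown for BRSST+sgLuc (blue) and BRSST+sgEzh2 (red). Prss34 lies at -4.76 and -5.08, and Car1 at 2.58 and 0.81.

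Lymphoid, basophil and dendritic cell lists were lower as groups in BRSST+sgLuc marrow. Of 20 measured B lineage genes 18 fell (19 adjusted over the list alone), with a median of log2 -2.30 and camera adjusted p = 1.73e-11 (adjusted p = 0.226 with an estimated correlation). Of 17 T and NK genes 10 fell (14 adjusted over the list alone), led by Klrb1c (-2.99 ± 0.73), Ncr1 (-2.80 ± 0.76) and Il2rb (-2.67 ± 0.64), receptors of natural killer cells, and Cd3g (-2.53 ± 0.64) of the T cell receptor complex. Of 10 mast cell, basophil and eosinophil genes 7 fell (8 adjusted over the list alone), among them Fcer1a, a chain of the IgE receptor (-3.10 ± 0.22), and Mcpt8, a basophil protease (-2.19 ± 0.19). Of 17 dendritic cell and MHC class II genes 8 fell (12 adjusted over the list alone), with Ccr9 at -2.70 ± 0.23. Of 9 plasma cell genes 4 fell (7 adjusted over the list alone), among them Irf4 (-2.06 ± 0.33) and Sdc1 (-0.73 ± 0.19). Of 21 monocyte and macrophage genes 10 fell and 1 rose, Cd14 (12 and 1 adjusted over the list alone), with Cx3cr1 at -2.44 ± 0.29, Axl at -2.03 ± 0.50 and Ccr2 at -1.57 ± 0.33. Interferon response genes fell in 14 of 25 cases (17 adjusted over the list alone), with the antiviral gene Oas2 at -1.95 ± 0.30 and Usp18, an ISG15 protease, at -1.65 ± 0.27. Cholesterol synthesis genes fell in 8 of 17 cases (8 adjusted over the list alone), with Hsd17b7 at -1.25 ± 0.24 and Msmo1 at -0.91 ± 0.24. Camera adjusted p for these other 7 lists ran from 4.46e-08 to 0.000966. None of the 8 passed with an estimated correlation (adjusted p = 0.0666 for the basophil list, 0.313 for T and NK, 0.441 for monocytes and 0.226 for the other 5), while fry, which tests whether a list moves one way, called all 8 (adjusted p from 2.01e-06 to 0.0456). The call of Ncr1 ended without sgLuc replicate 1 (limma adjusted p = 0.0501). Its change was -3.55 without BRSST+sgLuc replicate 2.

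**Figure D3:**
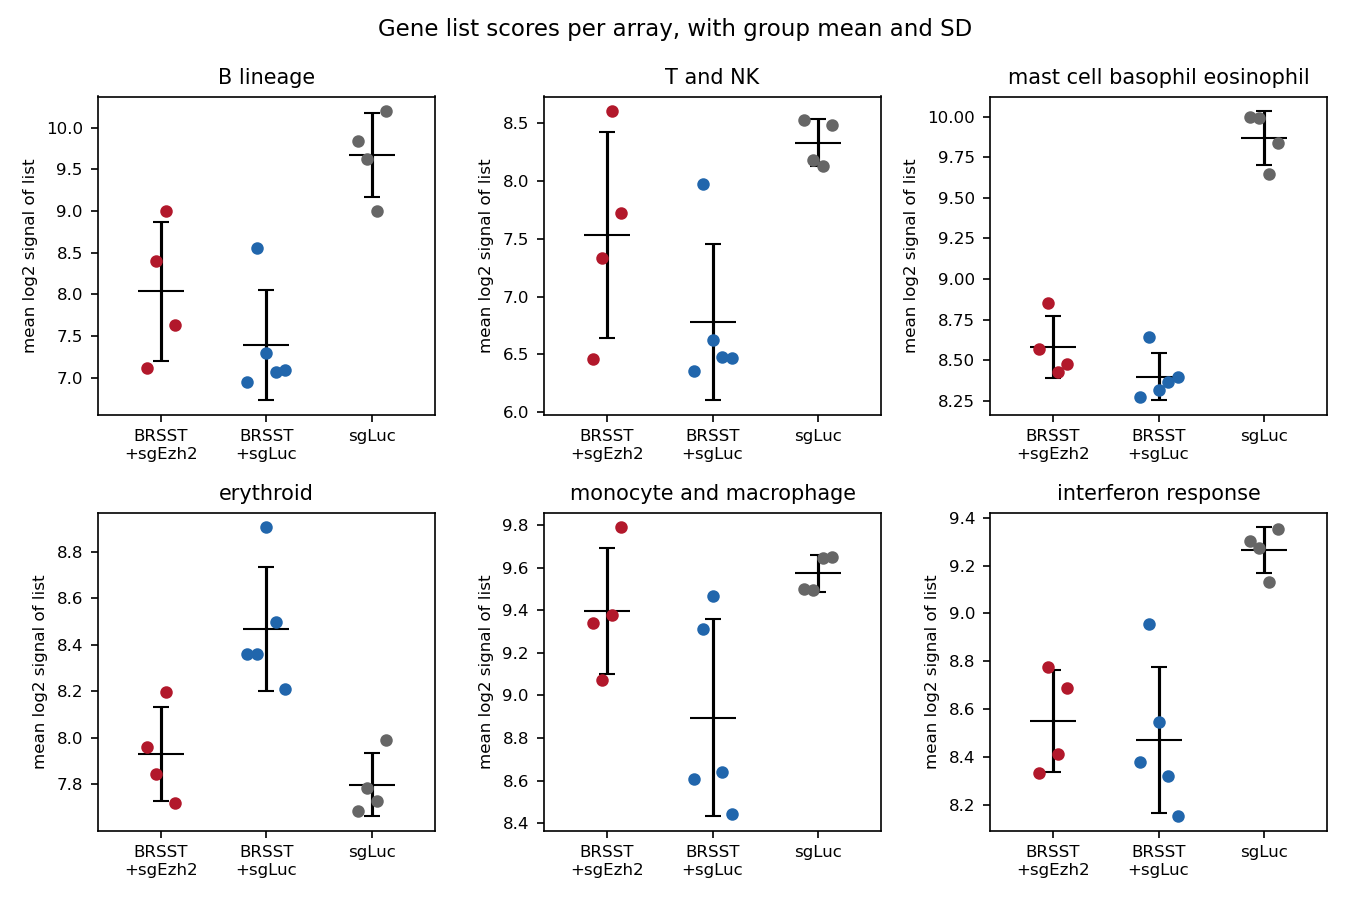
Mean log2 signal of the measured members of 6 gene lists on each array (points) by group, with the group mean and SD (black). The B lineage score averaged 8.04, 7.39 and 9.67 in BRSST+sgEzh2, BRSST+sgLuc and sgLuc, and the basophil list score 8.58, 8.40 and 9.87.

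The erythroid, oxidative phosphorylation and Hox lists were higher in BRSST+sgLuc marrow by camera, none of them with an estimated correlation (adjusted p = 0.226 for each). Of 17 erythroid genes 7 rose (10 adjusted over the list alone), with Car1, Rhag, Car2 (log2 1.20 ± 0.33) and Ank1 (0.91 ± 0.27) in front (camera adjusted p = 0.000322, and 0.226 with an estimated correlation). The Car2 call ended without sgLuc replicate 1 or 3 (limma adjusted p of up to 0.0615), and the Ank1 call without BRSST+sgLuc replicate 3 or 4 or sgLuc replicate 1 or 2 (up to 0.0859). Of 26 oxidative phosphorylation genes 12 rose and 1 fell (14 and 1 adjusted over the list alone), with Sdhd at 0.76 ± 0.10, Ndufb5 at 0.69 ± 0.10 and the fall, Sdha, at -0.71 ± 0.23 (camera adjusted p = 1.08e-05, and 0.226 with an estimated correlation). All 12 measured Hox genes and cofactors were higher and 5 rose (7 adjusted over the list alone): Hoxa5 by 0.75 ± 0.10, Hoxb7 by 0.64 ± 0.17, Hoxa6 by 0.55 ± 0.15, Hoxb2 by 0.38 ± 0.13 and Hoxb3 by 0.31 ± 0.10 (camera adjusted p = 0.00212, and 0.226 with an estimated correlation). Hoxa6 lost its call without sgLuc replicate 1 or 4 (up to 0.0658), and Hoxb2 and Hoxb3 without any of 6 or more arrays, BRSST+sgLuc replicates 1, 4 and 5 and sgLuc replicates 1, 2 and 4 among them (up to 0.136). Of 15 primary granule genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), with the protease Ctsg at 0.78 ± 0.10, the inhibitor Cst7 at 0.84 ± 0.13 and the fucosyltransferase Fut7 at -0.89 ± 0.11. That list passed narrowly (camera adjusted p = 0.0454, 0.428 with an estimated correlation) and lost its call without BRSST+sgLuc replicate 1, 2 or 3 or sgLuc replicate 1 or 4 (up to 0.0634). Ribosome biogenesis genes rose in 5 of 22 cases (5 adjusted over the list alone), with Wdr74 at 0.71 ± 0.15 (camera adjusted p = 0.00212, and 0.52 with an estimated correlation). Immediate early and heat shock genes rose in 6 and fell in 1 of 18 cases (6 and 1 adjusted over the list alone), with Jun at 0.95, Fosb at 0.88 ± 0.22, Fos at 0.68 ± 0.17 and the chaperone Hsph1 at -1.64 ± 0.25 (camera adjusted p = 0.013, and 0.52 with an estimated correlation). Fry called the erythroid, oxidative phosphorylation, Hox and primary granule lists (adjusted p from 0.000954 to 0.00542), and gave 0.113 for both others. The calls of Sdha and Jun ended without any of 7 and 6 arrays, BRSST+sgLuc replicates 1 and 4 and sgLuc replicates 1, 2 and 3 among both (limma adjusted p of up to 0.0971). Car2, Ank1 and Hoxb3 also lost theirs with the Y-linked class as a block (0.0593, 0.0607 and 0.0551).

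The PRC2 subunits and the myeloid tumour suppressors changed in single members, not as lists. Of 11 PRC2 subunits 2 fell (3 adjusted over the list alone), Ezh1, the paralog of Ezh2, at log2 -0.45 ± 0.14, and Jarid2, a PRC2 cofactor, at -0.34 ± 0.10 (camera adjusted p = 0.0744 for the list). Of 24 myeloid tumour suppressors 4 fell and 1 rose (3 and 1 adjusted over the list alone): Gata2, a stem cell transcription factor (-1.0 ± 0.26), Stag2, a cohesin subunit (-0.99 ± 0.30), Nf1, a RAS GTPase-activating protein (-0.77 ± 0.23), Runx1 (-0.47 ± 0.16) and U2af1, a splicing factor, at 0.69 ± 0.12 (0.0744). The calls of Ezh1, Jarid2, Stag2, Nf1 and Runx1 each ended without any of 4 to 7 arrays, BRSST+sgLuc replicate 1 and sgLuc replicates 1, 2 and 4 always among them (limma adjusted p of up to 0.119). Of 11 known PRC2-silenced genes Cdh1, the epithelial cadherin, fell (-1.43 ± 0.15) and Runx3 rose (0.86 ± 0.18), also when adjusted over the list alone (0.745). Stem and progenitor genes fell in 4 of 15 cases (4 adjusted over the list alone), with Angpt1 at -1.40 ± 0.33 and Erg at -0.86 ± 0.14 (0.0532). Mature neutrophil genes went both ways, with 5 rises and 9 falls among 23 (5 and 10 adjusted over the list alone, 0.202), Stfa1 and Stfa2 among the rises. P53 targets rose in 4 of 18 cases (4 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.29 ± 0.21 (0.202). Of 25 genes of G2 and M phase 5 fell and 1 rose (5 and 1 adjusted over the list alone), with the checkpoint kinase Bub1b at -1.29 ± 0.31 (0.0537), and of 25 S phase genes 2 rose, Chaf1b (0.70) and Cdt1 (0.54), with 0 adjusted over the list alone (0.745). Inflammatory and NF-kB genes had 3 rises and 4 falls among 18 (4 and 4 adjusted over the list alone, 0.814), with Cxcl2, a neutrophil chemokine, at 1.60 ± 0.35 and Ptgs2 at -1.22 ± 0.31. Glycolysis and hypoxia genes had 1 rise and 2 falls among 25 (1 and 2 adjusted over the list alone, 0.355), with Hk2 at -1.28 ± 0.22, Ndrg1 at -0.78 ± 0.14 and Egln3 at 0.75 ± 0.15. The Notch list had 2 falls among 9 (2 adjusted over the list alone, 0.177), with Lef1 at -1.58 ± 0.28, and fry, unlike camera, called it lower (adjusted p = 0.0106). The megakaryocyte list had 1 rise and 1 fall among 13 (1 and 1 adjusted over the list alone, 0.699), with Itgb3 at -0.66 ± 0.13 and Treml1 at 0.46. The stroma list had 1 fall among 6 (1 adjusted over the list alone, 0.745), with Pecam1 at -0.87 ± 0.22. The calls of Chaf1b, Cdt1 and Treml1 each ended without any of 6 to 8 arrays, BRSST+sgLuc replicates 1 and 3 and sgLuc replicates 1 and 2 always among them (limma adjusted p of up to 0.109). Chaf1b, Treml1, Gata2 and Ptgs2 lost theirs with the Y-linked class as a block (0.0622, 0.137, 0.0568 and 0.0594). Signs of the median, the mean and the test did not all match for the PRC2-silenced, mature neutrophil, stroma and inflammatory lists.

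BRSST+sgEzh2 marrow, set against sgLuc marrow to ask what both sets of guides change at once, had its largest falls in Prss34, Jchain and Siglech. The same limits of harvest and array batch apply. Prss34 fell by 5.08 ± 0.23 on the log2 scale (SE, n = 4 and 4), or 33.8-fold, Jchain fell by 4.64 ± 0.67 or 24.97-fold, and Siglech fell by 4.52 ± 0.61 or 22.9-fold. Cldn1, a tight junction protein (-3.49), Ifit1bl2, an interferon-induced gene (-3.37), the kinase Stk39 (-3.37), Tlr5 (-3.33), Fcer1a (-3.24), Atp1b1 (-3.19) and Ly6d, a marker of early B cells (-2.88), also fell. Retnla, a secreted product of alternatively activated macrophages, rose 24.8-fold (log2 4.63 ± 1.03, and 5.45 without BRSST+sgEzh2 replicate 2). Its sgLuc signals of 4.294 to 4.833 lay below the lower quartiles of those arrays (5.661 to 5.849), so the size of that fold is uncertain. The stefins Cstdc5, Stfa1, Stfa2, Cstdc6 and Csta2 rose by 2.76 to 3.36, and Pcdh7, a protocadherin, rose by 2.95 ± 0.24. Fabp7, a fatty acid-binding protein (2.90 ± 0.66), Ptprm, a receptor phosphatase (2.89 ± 0.36), and Ryk (2.68 ± 0.15) were other large rises among genes whose groups did not overlap. Ptprm with sgLuc (4.835 to 5.688) and Ifit1bl2 with BRSST+sgEzh2 (4.787 to 5.209) also lay below the lower quartiles of their arrays. Their folds, and those of other genes with signals this low, are uncertain in size too. Limma adjusted p was 2.97e-08 for Prss34, 2.35e-07 for Ryk and 0.0119 for Retnla. In all, 993 of 10601 genes passed limma's test, 584 higher and 409 lower, and 120 rose and 156 fell by at least 2-fold. The excess of rises did not hold throughout: 414 were higher and 425 lower without BRSST+sgEzh2 replicate 4, and 902 and 972 in the high Y-linked class. Groups did not overlap for 23.3% of genes, against 2.86% by chance. The count was 610 or 597 without BRSST+sgEzh2 replicate 1 or 2, 519 or 588 without sgLuc replicate 1 or 2, and 232 with the 3 cell type scores as covariates. The Ly6d call ended without BRSST+sgEzh2 replicate 1, 2 or 4 or sgLuc replicate 1, 2 or 4 (adjusted p of up to 0.0776). Its change was -3.64 without BRSST+sgEzh2 replicate 3.

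B lineage, basophil, dendritic cell and interferon lists were lower in BRSST+sgEzh2 marrow than with sgLuc. Of 20 B lineage genes 7 fell (17 adjusted over the list alone), with Vpreb3 at log2 -2.98 ± 0.66 (-3.80 without BRSST+sgEzh2 replicate 2) and Il7r at -2.22 ± 0.56, and Il7r lost its call without BRSST+sgEzh2 replicate 1 or sgLuc replicate 1, 2 or 4 (limma adjusted p of up to 0.0713). Of 10 mast cell, basophil and eosinophil genes 5 fell (5 fell and 1 rose adjusted over the list alone), with Mcpt8 at -2.45 ± 0.20 and Prg2, an eosinophil granule protein, at -1.24 ± 0.25. Of 17 dendritic cell and MHC class II genes 7 fell (12 adjusted over the list alone), with Ccr9 at -2.82 ± 0.24. Of 25 interferon response genes 12 fell (15 adjusted over the list alone), with Oas2 at -1.70 ± 0.32 and Usp18 at -1.55 ± 0.28. Plasma cell genes fell in 3 of 9 cases (4 adjusted over the list alone), with Irf4 at -1.72 ± 0.35. Camera adjusted p was 1.73e-11, 2.5e-06, 1.31e-10, 9.75e-11 and 0.000915 for these 5 lists in turn, fry called each (7.35e-06 to 0.00744), and with an estimated correlation the adjusted p was 0.0898 for the basophil list and 0.223 for the other 4. No member of the T and NK list passed, over all genes or adjusted over the list alone, though all 17 were lower (camera adjusted p = 0.000392, 0.524 with an estimated correlation, fry 0.204). Its score was 7.53 ± 0.89 (SD, n = 4) with BRSST+sgEzh2 against 8.33 ± 0.20 (SD, n = 4) with sgLuc. BRSST+sgEzh2 replicate 3, at 8.601, lay above every sgLuc array (up to 8.523), and the rest of its group reached at most 7.718. Without that array Zap70 and Cd8b1, at -0.84 and -1.30 over all arrays, passed at -1.03 and -1.98 (limma adjusted p = 0.0215 and 0.000512).

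Known PRC2-silenced genes had 3 rises and 1 fall among 11 in BRSST+sgEzh2 against sgLuc (3 and 1 adjusted over the list alone). Plag1 rose by log2 2.07 ± 0.24, Igf2bp3 by 1.496 ± 0.13 and Runx3 by 0.66 ± 0.19, and Cdh1 fell by 1.36 ± 0.15. The list passed (camera adjusted p = 0.033, 0.48 with an estimated correlation), but lost its call without BRSST+sgEzh2 replicate 1 or sgLuc replicate 2 or 4 (up to 0.0699). Runx3 lost its call without any array except BRSST+sgEzh2 replicate 2 (limma adjusted p of up to 0.117). Pbx3, a Hox cofactor, rose by 1.99 ± 0.42, the 1 rise among 12 genes of its list (1 adjusted over the list alone, camera adjusted p = 0.178). Ezh2 was the only call among 11 PRC2 subunits (1 fall over all genes, 2 adjusted over the list alone, 0.105) and among 24 myeloid tumour suppressors (1 adjusted over the list alone, 0.256). Oxidative phosphorylation genes rose in 7 of 26 cases (8 adjusted over the list alone), with Ndufv1 at 0.54 ± 0.12 (camera adjusted p = 0.000345, 0.48 with an estimated correlation). Of 22 ribosome biogenesis genes 2 rose (6 adjusted over the list alone), Pes1 at 0.61 ± 0.15 and Wdr74 at 0.58 ± 0.16, and the list passed (camera adjusted p = 5.13e-05, 0.524 with an estimated correlation). Pes1 lost its call without BRSST+sgEzh2 replicate 2 or sgLuc replicate 2 or 3 (limma adjusted p of up to 0.0598), and Wdr74 without any array except BRSST+sgEzh2 replicate 4 and sgLuc replicate 4 (up to 0.12). Erythroid genes gave 1 rise among 17, Fech, the last enzyme of heme synthesis, at 0.71 ± 0.12 (1 adjusted over the list alone, camera adjusted p = 0.764). P53 targets rose in 5 of 18 cases (5 adjusted over the list alone), with Pmaip1 at 1.18, Perp at 1.09 ± 0.20 and Cdkn1a at 1.08 ± 0.22 (camera adjusted p = 0.105), and Pmaip1 lost its call without BRSST+sgEzh2 replicate 2 or 3 or sgLuc replicate 1, 2 or 3 (limma adjusted p of up to 0.106).

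Primary granule genes gave 5 rises and 2 falls among 15 in BRSST+sgEzh2 against sgLuc (7 and 3 adjusted over the list alone), with Cst7 at log2 0.87 ± 0.14, Ctsg at 0.79 ± 0.10 and Nkg7 at -0.94. Mature neutrophil genes gave 3 rises, the stefins Stfa1, Stfa2 and Stfa3, and 4 falls among 23 (4 and 9 adjusted over the list alone), with Mmp25, a neutrophil membrane protease, at -1.54 ± 0.23. Immediate early and heat shock genes gave 4 rises and 1 fall among 18 (4 and 1 adjusted over the list alone), with Jun at 1.04, Fosb at 1.04 ± 0.23 and Hsph1 at -1.25 ± 0.27. Nkg7 and Jun each lost their call without any of 6 arrays, BRSST+sgEzh2 replicate 4 and sgLuc replicates 1, 2 and 3 among both (limma adjusted p of up to 0.122). Of 17 cholesterol synthesis genes 2 fell (3 adjusted over the list alone), with Mvd at -0.65 ± 0.13. Of 25 genes of G2 and M phase 0 passed, also adjusted over the list alone. Camera adjusted p was 0.0483, 0.0413, 0.04, 0.0347 and 0.0344 for these 5 lists, and 0.524, 0.572, 0.654, 0.524 and 0.733 with an estimated correlation. Each lost its call without some arrays: primary granules without BRSST+sgEzh2 replicate 1, 2 or 3 or sgLuc replicate 1 or 4 (up to 0.0897), neutrophils without any but BRSST+sgEzh2 replicate 4 and sgLuc replicate 3 (up to 0.132), and immediate early genes without BRSST+sgEzh2 or sgLuc replicate 2 or 3 (up to 0.192). The G2 and M list lost its call without BRSST+sgEzh2 replicate 3 or sgLuc replicate 2 or 4 (up to 0.449), and cholesterol synthesis without BRSST+sgEzh2 replicate 1 or sgLuc replicate 3 (up to 0.066). The neutrophil list had a median of -0.17 beside a mean of 0.12, and signs of the median, the mean and the test did not all match for the erythroid, stroma and inflammatory lists either. Of 21 monocyte and macrophage genes 2 rose, Cd14 (2.44 ± 0.26) and F13a1, a clotting factor subunit (1.21 ± 0.24), and 2 fell, Cx3cr1 (-1.83 ± 0.30) and the complement gene C1qa (-1.93), with 2 and 3 adjusted over the list alone (camera adjusted p = 0.212). C1qa lost its call without BRSST+sgEzh2 replicate 1 or 2 (limma adjusted p of up to 0.0526).

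The calls of both BRSST groups against sgLuc were compared gene by gene. BRSST+sgLuc and BRSST+sgEzh2 shared 441 genes called higher and 357 called lower, among them Prss34, Siglech, Jchain, Fcer1a, Stfa1 and Cd14, and 1 gene was called in opposite directions. Independent lists of these sizes would share 63.3 and 47.8 genes. Simulated unchanged groups against the same sgLuc arrays shared 0 and 0. With no change simulated, few or no genes can be called, so this cannot measure what the shared arrays add. With each group set against 2 different sgLuc arrays, 62 or 52 genes were shared among the higher calls (3.14 or 3.04 by independence) and 73 or 71 among the lower calls (4.81 or 4.77). Part of the excess can come from the shared control arrays, and from an array batch that would move both groups alike.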

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

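Each of 145 genes and 27 list scores was searched in each group for an array whose gap to its nearest neighbour is large against the group's range, and 30 of 516 such groups (5.81%) had one, where chance gives about 1 in 20. The genes include some chosen after their values were seen. BRSST+sgLuc replicate 2 accounts for 9 of the 30, BRSST+sgLuc replicate 5 and sgLuc replicate 3 for 4 each. Several genes and scores on 1 array belong to the same cell types, so they are not separate events.

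BRSST+sgLuc replicate 2 had the highest log2 signal of its group for Ncr1 (9.104, next 5.523), Fcrla (10.09, next 6.909), Ly6d (10.83, next 8.25), Cd22 (7.602, next 6.156) and Treml1 (8.234, next 7.786). Its B lineage score was 8.558 (next 7.3) and its T and NK score 7.967 (next 6.624), both the highest, while its G2 and M phase score of 9.255 (next 9.84) and its p53 target score of 8.432 (next 8.835) were the lowest. BRSST+sgLuc replicate 5 was lowest for Ces2g (10.05, next 11.29), Oas2 (6.524, next 7.626), Syngr1 (9.427, next 10.06) and the cholesterol synthesis score (7.972, next 8.33). BRSST+sgLuc replicate 3 was highest for Mybl1 (7.325, next 6.215).

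In BRSST+sgEzh2, replicate 1 was lowest for Klrb1c (4.349, next 7.526) and Il7r (4.881, next 6.975). Replicate 2 was highest for Cd209a (9.182, next 8.214) and lowest for Pfkl (8.638, next 8.878) and the glycolysis score (9.424, next 9.511). Replicate 3 was highest for Ly6d (10.69, next 7.768) and Pecam1 (8.835, next 8.547) and lowest for Msantd3 (9.769, next 9.947). Replicate 4 was highest for Cx3cr1 (7.522, next 6.728), Ptprm (8.801, next 8.045) and Csta2 (11.57, next 11.39).

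In sgLuc, replicate 3 was lowest for Mybl1 (7.706, next 8.7), the myeloid tumour suppressor score (9.661, next 9.831) and the plasma cell score (9.181, next 9.357), and highest for Itgb3 (9.283, next 8.923). Replicate 1 was lowest for Ctsg (11.65, next 11.79).

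Array features without a gene symbol also carried signal. Of 2631 such features 1164 were bright enough to test, and limma called 9 of them between BRSST+sgEzh2 and BRSST+sgLuc (7 higher), 269 between BRSST+sgLuc and sgLuc (152 higher) and 130 between BRSST+sgEzh2 and sgLuc (80 higher).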

How the results depend on the processing

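The fits with Y-linked class, list scores or both BRSST+sgLuc replicates 2 and 5 left out were chosen after seeing the data. Among the genes and called lists rerun, no gene's change and no direction of a list test turned except with list scores as covariates, or for Stard4 in the high Y-linked class. The median of the PRC2-silenced list between both BRSST groups, 0.0287, did turn: to -0.000586 with no filter, -0.032 with quantile normalization, -0.037 with equal medians, -0.0194 without BRSST+sgEzh2 replicate 1, -0.00438 without BRSST+sgLuc replicate 2 and -0.0342 without BRSST+sgLuc replicates 2 and 5. That of the erythroid list in BRSST+sgLuc against sgLuc turned to -0.0889 with list scores as covariates. The cause of a moved value was not tested where no construction shows it. Arrays have no depth, and compression near the top and bottom of the signal can limit fold changes. The mean of a gene's rows ended 0 of 227 gene results, trended and robust variance 2, equal medians 4, quantile normalization 8, no filter 14, only the 2 groups compared 31, the replicate block 31, the Y-linked class as a block 20, the high class alone 16 and the low class alone 25 of 38. The first of these could hardly end any, since none of the genes taken by the naming rule had several rows. List scores as covariates ended 146 of the 227 and turned 30, and leaving out BRSST+sgLuc replicates 2 and 5 ended 15 of 147. Of the 20 ended by the Y-linked class as a block, 17 belong to BRSST+sgLuc against sgLuc, where 2 of 5 and 4 of 4 arrays are of the high class.

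Between BRSST+sgEzh2 and BRSST+sgLuc the 83 changed genes became 128 without a filter, 36 with the stricter filter (fewer genes tested) and 1039 with array quality weights. They became 17 with only the 2 groups compared, 37 at 2-fold or more and 18 at an adjusted p under 0.01. With the Y-linked class as a block the count was 170. It was 722 in the high Y-linked class, with 2 and 2 arrays compared and 4 sgLuc arrays in the fit. In the low class, with 2 and 3 arrays and no sgLuc array, it was 1. The count was 143 without BRSST+sgLuc replicates 2 and 5, and 2 with list scores as covariates. Between BRSST+sgLuc and sgLuc the 2389 became 4879 with weights, 477 at 2-fold, 1102 at 0.01, 3655 in the high Y-linked class and 7 with list scores. Between BRSST+sgEzh2 and sgLuc the 993 became 2976 with weights, 1822 with only the 2 groups, 276 at 2-fold, 398 at 0.01, 1874 in the high Y-linked class and 232 with list scores. Weights moved Ezh2 past the threshold, at -1.224 (limma adjusted p = 0.00581) against BRSST+sgLuc and -0.6298 (0.0196) for BRSST+sgLuc against sgLuc.

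Leaving out 1 array gave 22 to 377, 1481 to 2839 and 519 to 839 changed genes in the 3 comparisons in that order. Ezh2 ranged from -1.214 to -0.8122 (limma adjusted p 0.0414 to 0.203), -0.6846 to -0.3575 (0.066 to 0.321) and -1.72 to -1.338 (0.00337 to 0.0132).

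Replicate numbers do not pair the samples: of 4 pairs of deviations, 1, 0 and 3 had a correlation above 0.1, and 0, 0 and 1 arrays correlated best with their own number. With the replicate number as a block the count between BRSST+sgEzh2 and BRSST+sgLuc was 28 and the others moved by less than 1.5 times.

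With B lineage, monocyte and erythroid scores as covariates, which differ between the groups and are themselves 3 of the lists tested, standard errors grew (Ezh2 from 0.263 to 0.441 against BRSST+sgLuc) and directions turned. For BRSST+sgEzh2 against BRSST+sgLuc, Il2rb was at -0.4207, Il7r at -0.6515 and Zap70 at -0.001216, and the medians were 0.107 for the monocyte list (turned by camera's test, not its median), -0.00607 for B lineage and -0.223 for T and NK. For BRSST+sgLuc against sgLuc, Ezh2 was at 0.4048, Angpt1 at 1.329, Arntl 0.05698, Axl 0.0528, Bst2 0.2843, Car1 -1.248, Cd209a 0.3007, Cd3g 1.218, Cdt1 -0.3219, Clock 0.2847, Cxcl2 -0.132, Egln3 -0.2566, Fcrla 2.778, Il2rb 1.923, Il7r 0.7538, Jun -0.2328, Klrb1c 2.822, Msmo1 0.8065, Nf1 0.2719, Nop16 -0.1175, Pmaip1 -0.8557, Prg2 0.02386, Rtp4 1.622, Slamf7 0.4146 and Usp18 0.3659, none past the threshold, and Ncr1 at 4.436, which passed (limma adjusted p = 0.0229). List medians there were -0.121 for primary granules, 0.0528 for monocytes, -0.26 for B lineage (turned by the test), 0.297 for dendritic cells, 0.0281 for interferon response and -0.163 for immediate early genes, and 0.866 for T and NK and -0.497 for ribosome biogenesis, which passed the other way (camera adjusted p = 0.01 and 0.013). For BRSST+sgEzh2 against sgLuc, Cd22 was at 0.1446, Il7r at 0.1023, the T and NK median at 0.479 (passed the other way, 0.0144) and Ezh2 at -1.081, no longer past the threshold (limma adjusted p = 0.133). In the high Y-linked class Stard4 was at -0.1397 in the comparison of both BRSST groups.

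No called list passed with an estimated correlation, and fry kept 21 of the 37 list calls. Quantile normalization ended 4 of the 37, weights 4, the stricter filter 8 of 28 and the high Y-linked class 9 of 37.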

Other observations

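Except for Plag1, the genes of this part were chosen after their values were seen, as were the comparison of the raised genes with sgLuc, the count of neighbours, and the fits with Y-linked class or list scores. Among the tested genes, in the gene order of GRCm38.p6, Plag1 comes next to Chchd7 and Chchd7 next to Penk. Untested genes can lie between them. All 3 rose in BRSST+sgEzh2 against BRSST+sgLuc. Plag1 rose by log2 2.35 ± 0.22 (SE, n = 4 and 5), Chchd7, a mitochondrial protein gene, by 0.74 ± 0.12 and Penk, the precursor of enkephalin peptides, by 2.597 ± 0.53 (limma adjusted p = 0.000136, 0.014 and 0.0428). Chchd7 lost its call without BRSST+sgEzh2 replicate 4 (0.0517), and Penk without BRSST+sgEzh2 replicate 1, 3 or 4 or BRSST+sgLuc replicate 1, 4 or 5 (up to 0.134), and both with only the 2 groups compared (0.0775 and 0.144).

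Clock and Arntl, partners in the circadian transcription factor, rose in BRSST+sgEzh2 against BRSST+sgLuc by log2 1.12 ± 0.19 and 1.34 ± 0.22 (SE, n = 4 and 5, limma adjusted p = 0.014 for each). Both lost their call without BRSST+sgEzh2 replicate 4 (0.0585 and 0.067), and Clock with only the 2 groups compared (0.0985). For BRSST+sgLuc against sgLuc, Arntl fell by 0.70 ± 0.22 (0.0363), a call lost without any of 6 arrays, BRSST+sgLuc replicates 1, 4 and 5 and sgLuc replicates 1, 2 and 4 (up to 0.113), and with the Y-linked class as a block (0.0594). Clock was at -0.51 ± 0.19 there (0.0615, and 0.0172 to 0.0258 without BRSST+sgLuc replicate 2 or 3). Fkbp5, Klf9 and Mt1, known targets of the glucocorticoid receptor, rose in both BRSST groups against sgLuc. For BRSST+sgLuc (SE, n = 5 and 4) Fkbp5 rose by 1.66 ± 0.16, Klf9 by 2.44 ± 0.21 and Mt1 by 2.28 ± 0.19 (limma adjusted p = 1.85e-05, 7.06e-06 and 7.06e-06). For BRSST+sgEzh2 (n = 4 and 4) they rose by 1.39 ± 0.16, 1.98 ± 0.22 and 1.91 ± 0.20 (0.00012, 7.52e-05 and 5.66e-05). Per1 (1.33 ± 0.24 and 1.43 ± 0.25) and Tsc22d3 (0.81 ± 0.21 and 0.90 ± 0.22) rose too (0.00179, 0.00279, 0.0132 and 0.02), and Tsc22d3 lost its call in BRSST+sgEzh2 without BRSST+sgEzh2 replicate 2 or sgLuc replicate 2 or 4 (up to 0.0693), and in both groups within the high Y-linked class, which has fewer arrays (0.0614 and 0.0621).

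For the 71 genes that rose in BRSST+sgEzh2 against BRSST+sgLuc, with a median of log2 0.963, the sex of the cells was argued against as the whole cause. The median was 0.967 with the Y-linked class as a block and all 71 passed. With 2 of 4 and 2 of 5 arrays in the high class, that block could move the median little. The argument rests on that near-even division of the classes. Within the high and the low class alone the medians were 1.06 and 0.921, with all 71 higher in each. The 71 were chosen as higher on these same arrays, so that direction was largely fixed in advance. A different mix of marrow cells stays open: with list scores as covariates the median was 0.689 with a typical SE of 0.294, 70 of 71 kept their direction and 1 passed. Low values in BRSST+sgLuc alone stay open too. Against sgLuc the median was 0.47, 55 of 71 were higher, and 30 were called higher and 3 lower. In BRSST+sgLuc 35 of the 71 were called lower than in sgLuc. These comparisons reuse arrays on which the 71 were chosen, which by itself favours both results. Joint rises of neighbours among the tested genes gave 2 adjacent pairs, both at Plag1, Chchd7 and Penk. Random draws gave 0.477 on average (one-sided permutation p = 0.0826), which leaves that open. An effect of the Ezh2 guide, which the design names, was not tested apart from these.

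For Clock and Arntl, with a mean rise of log2 1.22, a different time of day at harvest could account for the change. It would lower the clock output genes that run opposite to Arntl, and 3 of the 6 were measured, Nr1d1, Dbp and Tef, with a difference in their mean of -0.1 (95% interval -0.344 to 0.144, exact permutation p = 0.405). That interval reaches below -0.25, the bound set beforehand for excluding it, so this stays open. A different mix of cells stays open as well, with a mean of 0.8 for the pair once list scores were covariates.

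For Fkbp5, Klf9 and Mt1, with a mean rise of log2 1.94 in both BRSST groups, glucocorticoid exposure is a candidate explanation. Of 9 other glucocorticoid-induced genes 7 were measured, and their mean was higher by 0.385 (95% interval 0.139 to 0.631, two-sided exact permutation p = 0.00699), which met the test set beforehand, and BRSST+sgLuc alone gave 0.419 (exact permutation p = 0.0317) and BRSST+sgEzh2 alone 0.343 (0.0857). Of the 7, Per1 and Tsc22d3 passed in both groups, and Sgk1, Mt2, Cebpd, Ddit4 and Dusp1 passed in neither, so glucocorticoid exposure remains a hypothesis. The sex of the cells was argued against, since the mean rise was 2.05 within the high Y-linked class. A separate batch of sgLuc arrays stays open. The sources used here record no batch, and only the label numbers, which restart for sgLuc, hint at one.

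Other splits of the same arrays into groups of the same sizes bear on the counts of changed genes. For BRSST+sgEzh2 against BRSST+sgLuc, 100 of 126 possible splits were run, and 3, the real one included, called at least the real 83 genes. That share lies below 0.05, the bound set beforehand. It comes from a sample of splits and from a count that rested on single arrays, so chance is not excluded. The highest other split called 488, with BRSST+sgLuc replicates 1, 2, 4 and 5 against BRSST+sgLuc replicate 3 and all of BRSST+sgEzh2. That count, several times the real one, points to a structure of the samples: the split differs from the real one only by BRSST+sgLuc replicate 3, without which the real comparison called 377. For BRSST+sgLuc against sgLuc 1 of 100 splits, the real one, reached 2389 (highest other 1745), again out of 126 possible. For BRSST+sgEzh2 against sgLuc 1 of all 35, the real one, reached 993 (highest other 5). A chance division of the arrays is argued against at 0.05 for BRSST+sgEzh2 against sgLuc. For BRSST+sgLuc against sgLuc that holds only among the splits run.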
